A study of Mus musculus with 10 samples.

How the data were processed

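RNA sequencing libraries of mouse S1BF at postnatal day 17 were made from 4 Loxp, 2 Hetero and 4 cKO samples. Per the labels, tissue was frozen quickly, RNA was extracted with Trizol, and 3 µg of it went into each library with the NEBNext Ultra RNA kit. The deposited read counts per gene were made by the authors with featureCounts 1.5.0-p3 on mm10, per the submitters' processing notes. Their aligner, gene annotation and test tool are not given in the sources used here. Beside the counts, the authors deposited FPKM per gene and library, and the log2 fold changes, p-values and adjusted p-values of their own tests of cKO and Hetero against Loxp. The counts were used for each comparison; the FPKM served only to check scaling, and the authors' test columns were read beside the results.

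The counts were whole numbers and totalled 19332990 to 26086337 per library, with 2.80% to 3.68% of counts on mitochondrial genes. The ratio of counts to FPKM, divided by the library total, was 0.985 to 1.03 times that in Loxp 1. The chi-square per gene between libraries was 5.57 to 49.0 over all 45 pairs, above the value near 1 that sequencing the same library again would give, so no library was a duplicate of another. Gene coordinates came from GENCODE M21 (GRCm38, Ensembl 96), in which 52403 of 52636 gene IDs were found by ID. The table's own symbols were kept, of which 103 occur more than once; genes were handled by ID. Coordinates of the named loci are those of this annotation.

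Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr at its defaults, glmQLFit and glmQLFTest. All 10 libraries were fitted together with a mean per group, so that the spread of each gene was estimated over the 3 groups, and the contrasts were cKO against Loxp, Hetero against Loxp, and cKO against Hetero. Of 32197 genes with a count in at least 1 library, 18455 were tested, and the Benjamini-Hochberg adjusted p had to be under 0.05. The common biological coefficient of variation was 14.9% and the prior degrees of freedom 6.32. Levels are given as CPM with TMM-scaled library totals, and log2 CPM used a prior count of 2. Adjusted p-values in the text are from edgeR unless another tool is named. Exact permutation tests of single genes and list levels enumerated the 70 arrangements of 4 against 4 libraries, the 210 of 4 against 6, or the 15 of 4 against 2.

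The samples, the tests, 40 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists hold markers of cell types and genes of nuclear receptor signalling, activity, synapses, channels, stress and metabolism. Each was tested with camera (limma 3.58.1) on log2 CPM at its preset correlation of 0.01, adjusted over the lists with at least 5 tested genes. Camera asks whether the genes of a list move relative to other genes. It was repeated with a correlation estimated from the data. Fry, the other alternative, asks whether a set's genes move, on balance, one way, and it compares them with no other genes. Members were also counted with p adjusted over the list alone.

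Rxra and Neurod6 are named in each comparison. Other genes are named if past the threshold, with a mean log2 CPM over 0 and no overlap between groups, up to 12 higher and 12 lower by log2 fold change in cKO against Loxp and 8 and 8 elsewhere. Where fewer than 5 passed, the 5 with the smallest p are named as not passing. From each list reported, the 1 to 4 members with the smallest p are named. Gene models with a number or clone name only, and pseudogenes, were counted and not named by this rule. Genes called by DESeq2 or by the authors, and nuclear copies of mitochondrial genes, were named after their values were seen.

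The correlation of the Hetero and cKO responses was set against 100 simulations and against splits of the Loxp libraries between the contrasts. Each simulation drew all 10 libraries anew without group differences and with independent genes, and both contrasts shared the simulated Loxp libraries. Genes within 10 Mb of Rxra or Neurod6 were compared with all others by Fisher's exact test. As no gene passed the threshold, an unadjusted p under 0.05 was used for this, a choice made after the values were seen. Transcripts of the mitochondrial protein-coding genes were compared with nuclear transcripts by blastn, with copies called at an identity of at least 98% over at least 50% of the length. Sex balance was read from Xist and from Ddx3y, Eif2s3y, Kdm5d and Uty, which were counted as present at a mean log2 CPM above 0.

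The alternatives were DESeq2 size factors in edgeR, library size alone, no low-count filter, at least 1 CPM in 4 libraries, only the groups compared, the replicate number as a block, Xist as a covariate, 1 surrogate variable (sva 3.50.0), chromosomes X and Y left out, genes near the loci left out, DESeq2 1.42.0, limma-voom, windows of 5 and 20 Mb, and each library left out in turn. A robust prior, the newer residual deviances of edgeR, the control splits for the immediate early list and the grouping of Hetero with cKO were chosen after the values were seen. Where 1 Hetero library was left out, the other was assumed to vary like the other groups.

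The fit was tested on simulated data with 200 changed genes among 18455 in each of 3 simulations. In cKO against Loxp it recovered 42.0%, 64.7%, 86.7% and 95.3% of 150 genes changed by 1.5, 2, 4 and 8-fold, with 36 false calls over all simulations. In Hetero against Loxp it recovered 28.7%, 60.0%, 81.3% and 90.7%, with 32 false calls. Simulated genes vary independently of each other, which measured genes do not, so these rates may be higher than the measured data allow. Floxed exons and splice forms were not analysed here, since counts per gene cannot resolve them. Sequencing depth set no confidence interval for a single sample here, as values are compared between replicate libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.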

Results

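RNA was profiled from the barrel field of the primary somatosensory cortex (S1BF) of C57BL/6 mice at postnatal day 17. The 10 libraries fell into 3 genotypes. Loxp mice (n = 4) carried floxed Rxra, the gene of the retinoid X receptor alpha, without Cre. Hetero mice (n = 2) and cKO mice (n = 4) carried Nex-cre with a heterozygous and a full conditional deletion of Rxra. Nex-cre is a Cre knock-in at Neurod6 that acts in excitatory neurons of the cortex. Total counts per library were 20920228, 20485199, 26086337 and 25163805 in Loxp, 19332990 and 22198491 in Hetero, and 25184425, 23133301, 25997122 and 23982828 in cKO. Of 52636 genes in the table, 18455 passed the low-count filter and were tested. The labels do not state that each library came from its own animal, so p-values measure the spread between these samples.

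Rxra (ENSMUSG00000015846, chromosome 2, 27676440 to 27762957) was not lower in cKO at the level of the whole gene. Its CPM (counts scaled to a common library total) were 24.5, 21.6, 28.3 and 31.8 in Loxp, 23.2 and 26.4 in Hetero, and 29.0, 32.4, 29.3 and 32.0 in cKO. The means were 26.6 ± 4.43 in Loxp (SD, n = 4), 24.8 ± 2.26 in Hetero (SD, n = 2) and 30.7 ± 1.74 in cKO (SD, n = 4). The log2 fold change of Rxra was 0.21 in cKO against Loxp (SE 0.112, edgeR adjusted p = 1) and −0.10 in Hetero against Loxp (SE 0.139, edgeR adjusted p = 1). Leaving out 1 library at a time moved it from 0.12 (without Loxp 2) to 0.31 (without Loxp 4) in cKO, and from −0.19 (without Hetero 2) to 0.01 (without Loxp 4) in Hetero. An exact two-sided permutation test of cKO against Loxp gave p = 0.114, where 0.0286 was the smallest p that 4 against 4 libraries allowed. The counts are per gene and would include reads of any transcript that lacks the floxed part, and of cells without Cre. They therefore do not check whether the deletion took place.

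Neurod6 (ENSMUSG00000037984, chromosome 6, 55677822 to 55681263) was lower in both Cre groups. Its CPM were 66.7, 55.7, 61.9 and 34.9 in Loxp, 34.4 and 34.0 in Hetero, and 32.9, 22.9, 38.1 and 24.0 in cKO. The means were 54.8 ± 14.0 in Loxp (SD, n = 4), 34.2 ± 0.278 in Hetero (SD, n = 2) and 29.5 ± 7.30 in cKO (SD, n = 4). The log2 fold change of Neurod6 was −0.89 in cKO against Loxp (SE 0.193, edgeR adjusted p = 1) and −0.68 in Hetero against Loxp (SE 0.241, edgeR adjusted p = 1). An exact two-sided permutation test of the 6 Cre libraries against the 4 Loxp libraries gave p = 0.00952, with 0.00476 the smallest p possible. This grouping was chosen after the values were seen. The same test of cKO against Loxp gave an exact p = 0.0571. The library labelled Loxp 4 lay at the level of the Cre groups, and every direction against Loxp below includes it.

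**Figure D1:**
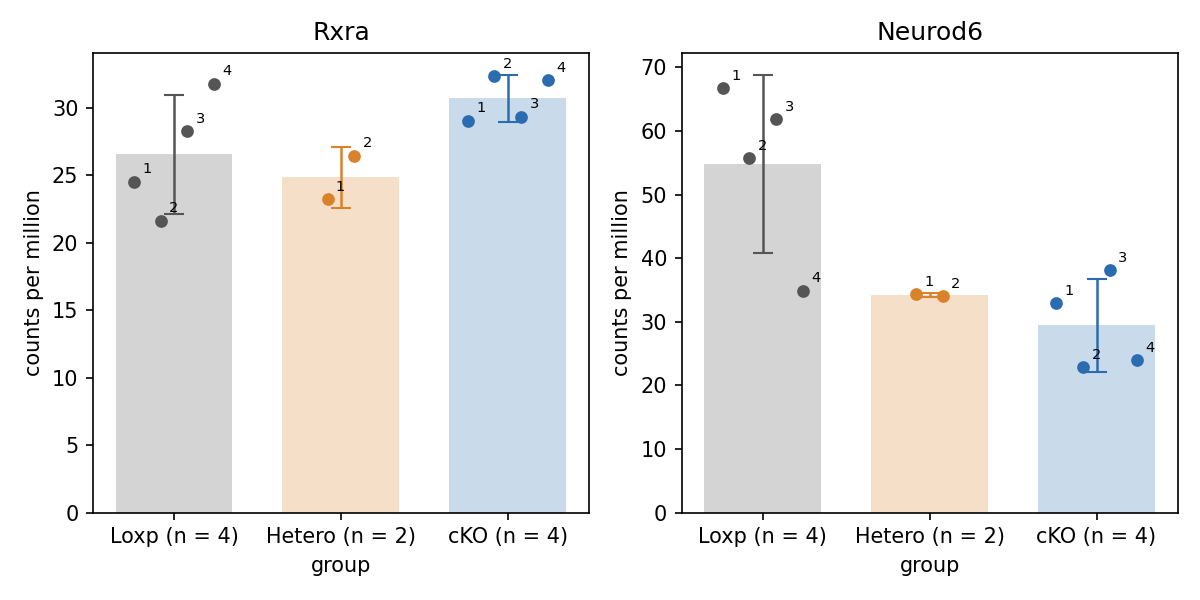
CPM of Rxra and Neurod6 in each library by genotype; bars give group means, error bars the SD, and points the libraries by replicate number. Rxra averaged 26.6 in Loxp and 30.7 in cKO, and Neurod6 54.8 and 29.5, with the library labelled Loxp 4 at 34.9.

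The comparison of cKO with Loxp asked which transcripts differ in S1BF when Rxra is deleted from excitatory neurons. The groups differ in Nex-cre as well, since Loxp mice carried no Cre. Immediate early and activity-regulated genes were lower in cKO. Arc (ENSMUSG00000022602) averaged 288 ± 80.0 CPM in cKO against 540 ± 207 in Loxp (SD, n = 4 and 4), a log2 fold change of −0.91 (SE 0.242, edgeR adjusted p = 1). Egr2 averaged 15.5 ± 3.32 against 31.0 ± 9.04 CPM, a log2 fold change of −1.003 (SE 0.213, edgeR adjusted p = 1). Egr3 averaged 188 ± 36.9 against 267 ± 39.5 CPM, a log2 fold change of −0.51 (SE 0.136, edgeR adjusted p = 1). Tiparp averaged 14.5 ± 2.09 against 20.02 ± 1.62 CPM, with each cKO library below each Loxp library and a log2 fold change of −0.47 (SE 0.113, edgeR adjusted p = 1). Of the 40 immediate early genes tested, 38 were lower, with a median log2 fold change of −0.34 and a mean of −0.35. The list passed camera with the preset correlation (adjusted p = 2.55e-16); it gave adjusted p = 0.807 with an estimated correlation. With p adjusted over the list alone, 15 of its genes passed, all lower; over all genes tested, 0 passed. Per library, the list level lay below the Loxp mean in 4 of 4 cKO libraries and below every Loxp library in 2 of them, since Loxp 2 lay at −0.34 on the log2 scale. An exact two-sided permutation test of the list levels gave p = 0.0857.

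**Figure D2:**
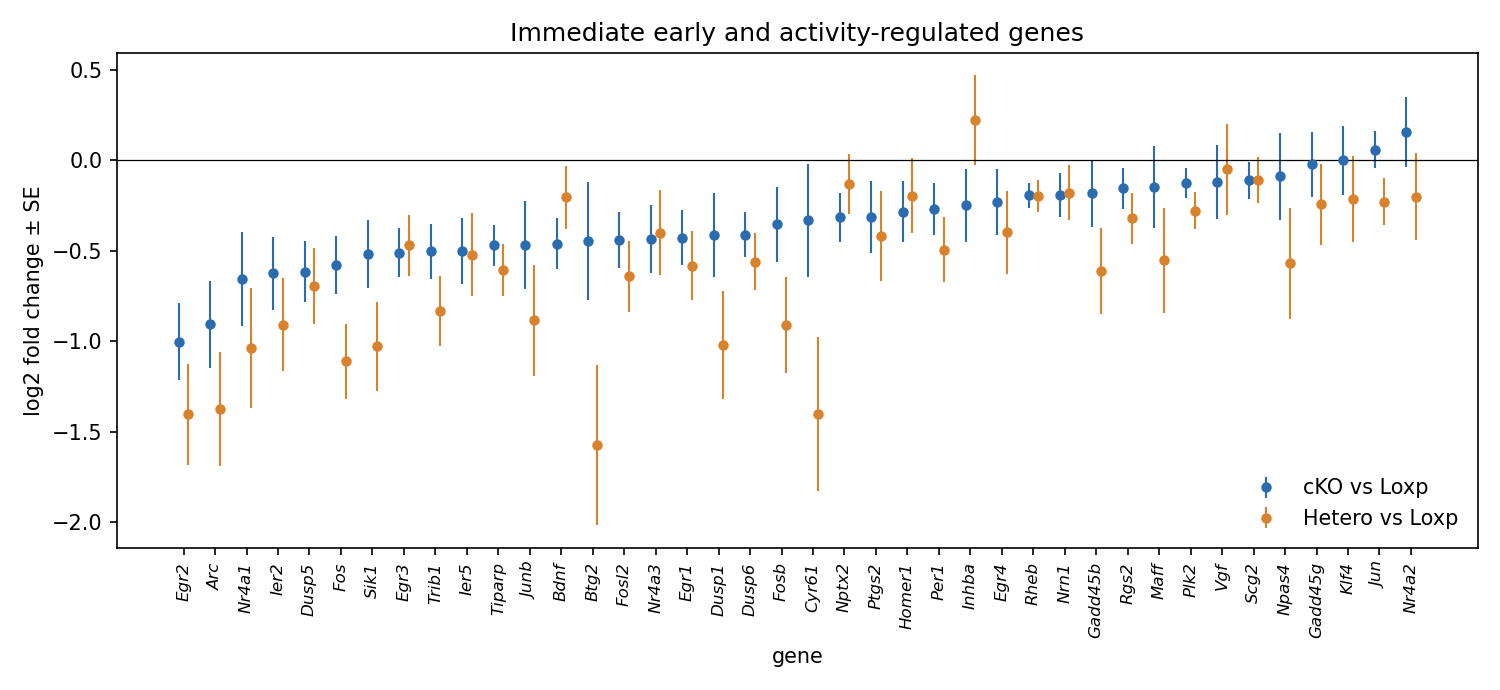
Log2 fold change against Loxp of the 40 immediate early and activity-regulated genes in cKO and in Hetero; points give edgeR estimates and error bars their SE. Genes are ordered by their value in cKO against Loxp, where 38 lay below 0; in Hetero against Loxp 39 did.

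No single gene passed the threshold in cKO against Loxp. edgeR called 0 of 18455 genes, with 466 at an unadjusted p under 0.05 (270 higher, 196 lower) where chance gives 922.8; DESeq2 and limma-voom called 0. Without cKO 2 edgeR called 1 gene, mt-Nd4l (log2 fold change 2.62), as it did with 1 surrogate variable. With the replicate number as a block it called 1 gene, Arc, at a log2 fold change of −0.88 (SE 0.0868, adjusted p = 0.00659; 9.23e-07 to 1 over the alternatives for Arc). With no low-count filter it called 32. Among genes with a symbol beyond a model number, the 5 smallest p, none of which passed, belonged to mt-Nd4l, Mid1, Egr2, Neurod6 and Arl4d. mt-Nd4l (ENSMUSG00000065947) averaged 30.6 ± 19.1 CPM in cKO against 6.04 ± 2.79 in Loxp, with each cKO library above each Loxp library and a log2 fold change of 2.33 (SE 0.426, edgeR adjusted p = 1). Mid1 averaged 18.2 ± 9.80 against 3.83 ± 1.65 CPM, a log2 fold change of 2.25 (SE 0.445, edgeR adjusted p = 1). A pseudogene of Mid1, Mid1-ps1, is also counted, so the count of Mid1 is uncertain. Arl4d averaged 32.7 ± 2.68 against 44.5 ± 5.85 CPM, with no overlap between the groups and a log2 fold change of −0.44 (SE 0.105, edgeR adjusted p = 1). The groups did not overlap for 284 genes (1.54%), where chance gives 2.86%.

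Besides the immediate early list, 5 of the 40 lists passed camera in cKO against Loxp, and each of them gave adjusted p = 0.963 with an estimated correlation. Heat shock and unfolded protein response genes were lower for 22 of 27 genes (median log2 fold change −0.12, adjusted p = 0.000242), with Dnajb5 at −0.22 (SE 0.0852) and Atf4 at −0.20 (SE 0.0916). Genes of the nuclear-encoded respiratory chain were lower for 70 of 79 (median −0.07, adjusted p = 0.000242), with Ndufc2 at −0.24 (SE 0.112). All 15 oligodendrocyte genes were lower (median −0.19, adjusted p = 0.000512), with Mbp at −0.19 (SE 0.118) and Trf at −0.45 (SE 0.218). Circadian clock genes were lower for 17 of 20 (median −0.09, adjusted p = 0.012), with Cry1 at −0.30 (SE 0.104) and Nfil3 at −0.36 (SE 0.128). Mitochondrially encoded genes were higher for 12 of 13 (median 0.15, mean 0.37, adjusted p = 0.000512), with mt-Atp8 at 0.86 (SE 0.404) and mt-Nd5 at 0.18 (SE 0.134). The cKO libraries on the list's side of the Loxp mean were 3 of 4 for heat shock, 4 of 4 for the respiratory chain, 3 of 4 for oligodendrocyte, 3 of 4 for clock and 4 of 4 for mitochondrially encoded genes. With p adjusted over the list alone, 1 mitochondrially encoded gene passed (mt-Nd4l) and 0 genes of the other four lists. The oligodendrocyte call was lost without cKO 2 (median −0.02, adjusted p = 0.615) and without the library labelled Loxp 4 (−0.13, adjusted p = 0.056). The respiratory chain call was lost without Loxp 1 (0.02, adjusted p = 0.6), as was heat shock (−0.08, adjusted p = 0.0803). The mitochondrially encoded call was lost without Loxp 3 (0.08, adjusted p = 0.0845). The clock call was lost without cKO 2 (−0.01, adjusted p = 0.574), Loxp 3 (−0.07, adjusted p = 0.202) and the library labelled Loxp 4 (−0.05, adjusted p = 0.142). The immediate early call was kept without each of the 8 libraries in turn (median −0.47 to −0.23). Medians moved by over 1.5 times with the call kept for mitochondrially encoded genes without Loxp 1 (0.09) and cKO 2 (0.07), and for the respiratory chain without Loxp 2 (−0.12). They did so for clock genes without cKO 3 (−0.14), and without cKO 4 for clock (−0.15), heat shock (−0.08) and oligodendrocyte genes (−0.33). Single genes moved as well, with Atf4 at −0.10 and mt-Nd5 at 0.09 without Loxp 1, Ndufc2 at −0.15 without cKO 1, and Mbp at −0.13 and Trf at −0.27 without cKO 2. mt-Nd5 stood at 0.30 without Loxp 2, and Mbp at −0.12 without the library labelled Loxp 4. Of the 46 genes named in this comparison, 28 moved by over 1.5 times without some library. The number of lists called went from 6 to 13 without cKO 4, 10 without cKO 2 and 4 without Loxp 3.

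The mitochondrially encoded values are uncertain for at least 6 of the 13 genes. mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6, mt-Nd3 and mt-Nd4 each have an annotated nuclear copy of at least 98% identity over at least 50% of their length, on chromosome 1. mt-Nd4l is 100% identical to Gm10222 over 99.0% of its length. The median log2 fold change in cKO against Loxp was 0.25 for those 6 genes and 0.09 for the other 7, of which 6 were higher. Among the other 7, mt-Atp8 was weakly counted, at 0.813 to 2.02 CPM in Loxp and 1.63 to 2.30 in cKO. Loxp 1, at 2.02, lay within the cKO range for mt-Atp8. By contrast, mt-Cytb averaged 5049 CPM in Loxp and 5471 in cKO. In Hetero against Loxp the medians were 0.22 and −0.02.

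Lists tied to the receptor itself did not pass in cKO against Loxp. Nuclear receptors that pair with RXR were higher for 7 of 15 genes (median −0.0041, adjusted p = 0.875), with Nr4a1, also an immediate early gene, at −0.66 (SE 0.260), Nr1h3 at 0.41 (SE 0.209), Nr1h4 at −1.45 (SE 0.809) and Thrb at −0.15 (SE 0.107). Retinoid metabolism and retinoic acid targets were higher for 9 of 19 (median −0.0041, mean 0.02, adjusted p = 0.875), with Aldh1a3 at −0.84 (SE 0.479), Ttr at 1.63 (SE 1.23) and Aldh1a1 at −0.23 (SE 0.180). LXR and PPAR lipid targets were higher for 13 of 26 (median 0.03, adjusted p = 0.565), with Cd36 at 1.35 (SE 0.657), Nr1h3 as above, Mylip at −0.19 (SE 0.103) and Abcg4 at 0.15 (SE 0.0883). Sterol biosynthesis genes were higher for 13 of 25 (median 0.02, mean −0.02, adjusted p = 0.51), with Ebp at −0.21 (SE 0.0992) and Cyp51 at −0.19 (SE 0.0921). Thyroid hormone targets in cortex were lower for 11 of 14 (median −0.14, adjusted p = 0.0563), with Nefh at −0.33 (SE 0.162). In these 5 lists 0 genes passed over all genes tested and 0 with p adjusted over the list alone. Nr1h4 was near the floor, at 0.0963, 0.813, 0.157 and 0.120 CPM in Loxp and 0.0394, 0.130, 0.0389 and 0.209 in cKO. Only Loxp 2 lay above the cKO range for Nr1h4. Single libraries moved most of these values. Without cKO 2, Aldh1a1 stood at −0.03, Cd36 at 0.79, Mylip at −0.13, Abcg4 at 0.08 and Nefh at −0.16. Aldh1a3 was at −0.54, Aldh1a1 at −0.35 and Thrb at −0.07 without cKO 4, and Ttr at 0.78 without cKO 1. Nr4a1 was at −0.33 and Aldh1a1 at −0.15 without the library labelled Loxp 4, Thrb at −0.08 without Loxp 2, and Abcg4 at 0.09 without Loxp 1. The 34 lists that did not pass had adjusted p from 0.0563 to 0.967; in 10 of them the median, the mean and the test differed in sign, and in 0 of the 6 that passed.

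The comparison of Hetero with Loxp asked the same of the heterozygous deletion with Cre present. Immediate early genes were lower in Hetero as well. Fos (ENSMUSG00000021250) averaged 31.2 ± 0.670 CPM in Hetero against 67.3 ± 16.2 in Loxp (SD, n = 2 and 4), with both Hetero libraries below every Loxp library and a log2 fold change of −1.11 (SE 0.207, edgeR adjusted p = 0.599). Egr2 averaged 11.7 ± 3.26 against 31.0 ± 9.04 CPM, a log2 fold change of −1.40 (SE 0.279, edgeR adjusted p = 0.599). Arc averaged 208 ± 38.2 against 540 ± 207 CPM, a log2 fold change of −1.37 (SE 0.314, edgeR adjusted p = 0.733). Of the 40 immediate early genes, 39 were lower, with a median of −0.54 and a mean of −0.58. Both Hetero libraries lay below every Loxp library in the level of the list. The list passed camera (adjusted p = 2.97e-25); it gave adjusted p = 0.297 with an estimated correlation. With p adjusted over the list alone, 21 of its genes passed, all lower; over all genes tested, 0 passed.

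Choroid plexus genes were higher in Hetero, and 1 library carried the difference. Ttr (ENSMUSG00000061808), the transthyretin gene, stood at 699 CPM in Hetero 2 and at 3.53 in Hetero 1, against 2.60 ± 1.93 in Loxp (SD, n = 4) and 7.997 ± 8.20 in cKO (SD, n = 4). Its log2 fold change in Hetero against Loxp was 7.08 (SE 1.35, edgeR adjusted p = 0.599). Clic6 was at 3.04 (SE 0.674) and Kl at 2.78 (SE 0.627), both with an edgeR adjusted p = 0.733, and Folr1 was at 2.32 (SE 0.568, edgeR adjusted p = 0.905). All 8 choroid plexus genes tested were higher (median 2.36, camera adjusted p = 1.51e-07); the list gave adjusted p = 0.75 with an estimated correlation. With p adjusted over the list alone, 6 passed. Without Hetero 2 the median was 0.21 and the adjusted p = 0.636.

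**Figure D3:**
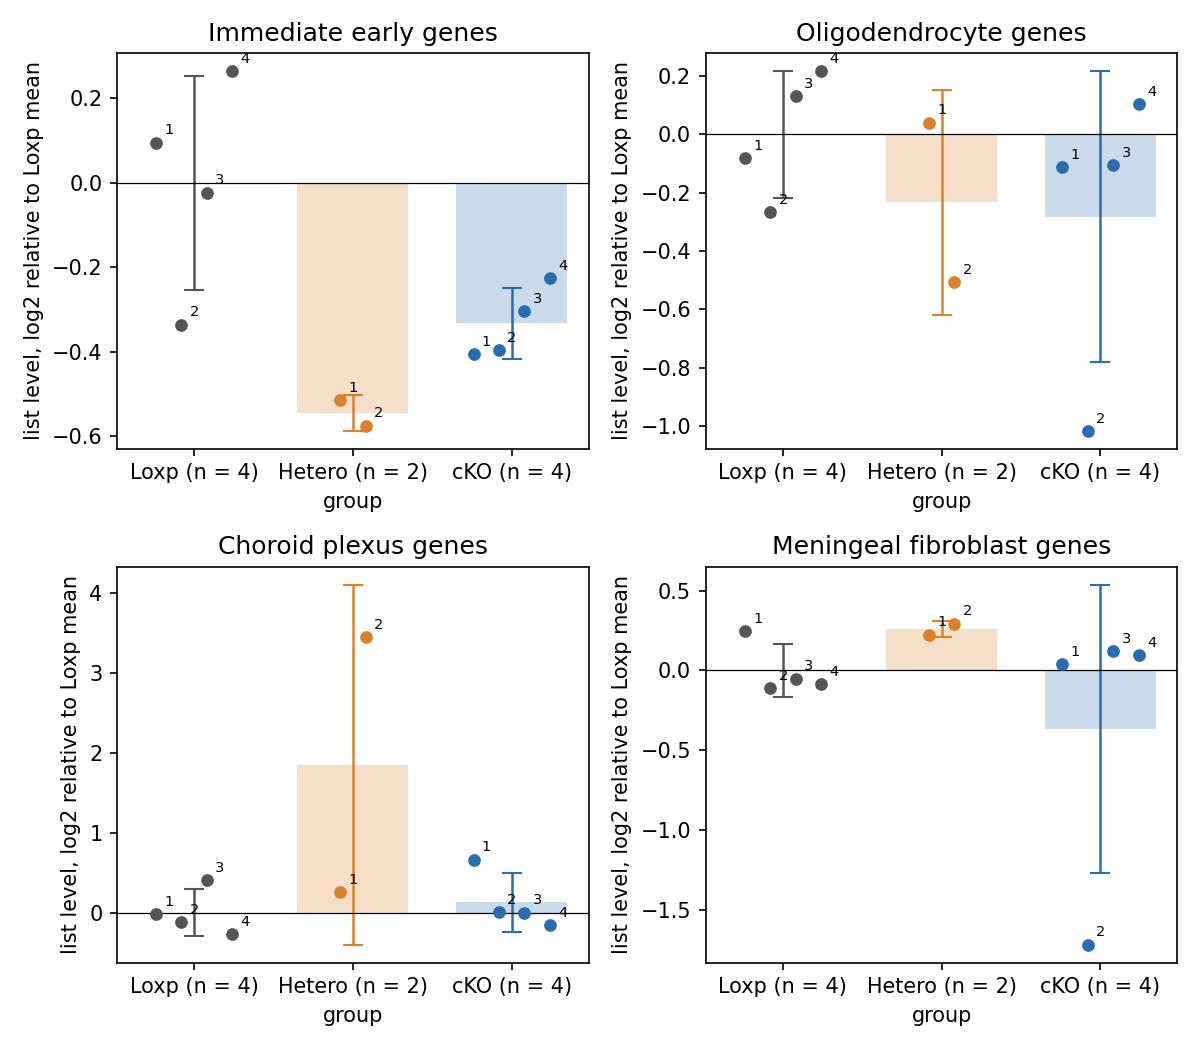
Mean level of 4 gene lists in each library, as log2 CPM relative to the Loxp mean, by genotype; bars give group means, error bars the SD, and points the libraries by replicate number. Immediate early genes lay at −0.33 in cKO and −0.54 in Hetero, Hetero 2 stood at 3.44 for choroid plexus genes, and cKO 2 at −1.02 for oligodendrocyte and −1.72 for meningeal fibroblast genes.

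No single gene passed in Hetero against Loxp by edgeR. It called 0 of 18455 genes, with 468 at an unadjusted p under 0.05 (237 higher, 231 lower), and limma-voom called 0. DESeq2 called 20, among them Fos, Egr2, Sik1 and Trib1, which were lower, and Ttr, Clic6, Otx2, Slc4a5 and Col8a2, which were higher. Without Hetero 1 edgeR called 15 genes, led by choroid plexus genes such as Kl and Ttr, with the variance of the lone Hetero 2 taken from the other groups. The 5 smallest p in edgeR, none of which passed, belonged to Fos, Egr2, Ttr, Slc4a5 and Col8a2. Slc4a5 averaged 3.33 ± 4.06 CPM in Hetero against 0.202 ± 0.0949 in Loxp, a log2 fold change of 3.998 (SE 0.747, edgeR adjusted p = 0.599). Col8a2 averaged 3.17 ± 2.25 against 0.803 ± 0.126 CPM, a log2 fold change of 1.98 (SE 0.389, edgeR adjusted p = 0.599). Hetero 2 carried most of both differences, as Slc4a5 stood at 0.460 CPM in Hetero 1 and 6.20 in Hetero 2, and Col8a2 at 1.58 and 4.77. With the replicate number as a block edgeR called 1 gene, Arc, and with no low-count filter 68. The groups did not overlap for 2105 genes (11.4%), where chance gives 13.3%.

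Another 12 lists passed camera in Hetero against Loxp and failed with an estimated correlation, where the adjusted p was 0.75 for astrocyte, 0.838 for ribosomal, 0.861 for respiratory chain and 0.819 for each of the other 9. Both Hetero libraries lay on the list's side of the Loxp mean in each but oligodendrocyte, where 1 of 2 did. Circadian clock genes were lower for 17 of 20 (median −0.21, adjusted p = 0.000105), with Per1 at −0.49 (SE 0.180) and Nfil3 at −0.48 (SE 0.161). Heat shock genes were lower for 25 of 27 (median −0.13, adjusted p = 0.000339), with Bag3 at −0.50 (SE 0.177). Astrocyte genes were lower for 13 of 15 (median −0.10, adjusted p = 0.00409), with Fgfr3 at −0.32 (SE 0.121) and S100b at −0.29 (SE 0.0994). Glucocorticoid-responsive genes were lower for 16 of 18 (median −0.20, adjusted p = 0.00618), with Per1 as above and Tsc22d3 at −0.44 (SE 0.169). Cytosolic ribosomal protein genes were lower for 65 of 76 (median −0.07, adjusted p = 0.00618), with Rpl13a at −0.35 (SE 0.148), Rpl17 at −0.50 (SE 0.220) and Rps14 at −0.22 (SE 0.103). Thyroid hormone targets were lower for 13 of 14 (median −0.15, adjusted p = 0.00643), with Thrsp at −0.84 (SE 0.265). All 15 oligodendrocyte genes were lower (median −0.22, adjusted p = 0.00676), with Mbp at −0.25 (SE 0.146), Trf at −0.46 (SE 0.274) and Mobp at −0.30 (SE 0.220). Microglia genes were lower for 12 of 13 (median −0.15, adjusted p = 0.00871), with C1qb at −0.27 (SE 0.136). Respiratory chain genes were lower for 63 of 79 (median −0.04, adjusted p = 0.0195), with Ndufc2 at −0.50 (SE 0.141). Sterol biosynthesis genes were lower for 20 of 25 (median −0.08, adjusted p = 0.0462), with Cyp51 at −0.24 (SE 0.114). Axon guidance and dendrite growth genes were higher for 39 of 51 (median 0.08, adjusted p = 0.0274), with Sema5b at 0.34 (SE 0.148). Retinoid genes were higher for 15 of 19 (median 0.13, mean 0.505, adjusted p = 0.0462), led by Ttr, the only one of them past the threshold when p was adjusted over the list alone. Ttr is also in the choroid plexus list, and stood at 699 CPM in Hetero 2 and 3.53 in Hetero 1. The level of the retinoid list was 0.62 in Hetero 2 and 0.19 in Hetero 1, which lay below Loxp 1 at 0.22. In the other 11 lists 0 genes passed over the list alone, and 0 passed over all genes in any list. Of the 57 genes named in this comparison, 29 moved by over 1.5 times without some library. Without Hetero 2, Nfil3 stood at −0.27, Mbp at −0.02, Trf at −0.25 and Mobp at −0.05, and without Hetero 1 Fgfr3 stood at −0.205, Mbp at −0.52, Trf at −0.69 and Mobp at −0.61. Per1 was at −0.33, Rpl17 at −0.25 and Mobp at −0.18 without the library labelled Loxp 4, and Rps14 at −0.14 without Loxp 1.

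Most of these calls were lost without some single library, and the number of lists called went from 14 to 9 without Hetero 1 and 7 without Hetero 2. Without Hetero 2, the adjusted p of camera was 0.426 for retinoid, 0.636 for sterol, 0.122 for thyroid, 0.0598 for axon guidance, 0.0521 for astrocyte and 0.113 for microglia genes. It was 0.698 for oligodendrocyte genes, whose median turned to 0.04. Without Hetero 1 it was 0.232 for axon guidance, 0.0961 for glucocorticoid, 0.616 for respiratory chain, 0.224 for ribosomal and 0.0524 for heat shock genes. Without Loxp 1 it was 0.234 for axon guidance and 0.077 for microglia genes; the respiratory chain (0.157) and ribosomal (0.675) medians turned to 0.04 and 0.02. Without Loxp 2 it was 0.209 for retinoid and 0.0725 for sterol genes, and without Loxp 3 it was 0.332 for sterol genes. Without the library labelled Loxp 4 it was 0.176 for retinoid, 0.107 for axon guidance, 0.0616 for glucocorticoid and 0.0881 for oligodendrocyte genes. Medians moved by over 1.5 times with the call kept for retinoid (0.21) and heat shock genes (−0.08) without Loxp 1, heat shock genes without Loxp 3 (−0.08) and oligodendrocyte genes without Hetero 1 (−0.52). The respiratory chain median did so without Loxp 2 (−0.10), Loxp 4 (−0.07) and Hetero 2 (−0.08), and the ribosomal median without Loxp 4 (−0.12). The immediate early and clock lists were called without each of the 6 libraries in turn, with medians of −0.61 to −0.46 and −0.26 to −0.16. The 26 lists that did not pass had adjusted p from 0.061 to 0.954; in 9 of them the median, the mean and the test differed in sign, and in 0 of the 14 that passed.

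The comparison of cKO with Hetero held Cre constant and set the full against the heterozygous deletion. Rxra averaged 30.7 CPM in cKO and 24.8 in Hetero, a log2 fold change of 0.30 (SE 0.140, edgeR adjusted p = 1). Neurod6 averaged 29.5 and 34.2 CPM, a log2 fold change of −0.21 (SE 0.235, edgeR adjusted p = 1). Immediate early genes were higher in cKO than in Hetero for 31 of 40 (median 0.20, camera adjusted p = 7.68e-05; adjusted p = 0.965 with an estimated correlation). Fos averaged 45.2 ± 7.97 CPM in cKO against 31.2 ± 0.670 in Hetero (SD, n = 4 and 2), a log2 fold change of 0.54 (SE 0.203), and Btg2 21.7 ± 5.10 against 9.94 ± 0.185 CPM, a log2 fold change of 1.13 (SE 0.435). Esd averaged 38.5 ± 1.92 against 24.4 ± 3.85 CPM, a log2 fold change of 0.66 (SE 0.130, edgeR adjusted p = 1). Each of these genes was higher in 4 of 4 cKO libraries than in either Hetero library. edgeR called 0 of 18455 genes, with 321 at an unadjusted p under 0.05 (180 higher, 141 lower), and limma-voom called 0; DESeq2 called 3, Slc4a5, Aqp1 and Esd. The 5 smallest p in edgeR, which did not pass, belonged to Esd and to Slc4a5 (log2 fold change −3.69), Col8a2 (−1.96), Aqp1 (−2.95) and Prlr (−2.40). Without Hetero 1 edgeR called 14, and with no low-count filter 39. The groups did not overlap for 1741 genes (9.43%), where chance gives 13.3%.

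Astrocyte and microglia genes were higher in cKO than in Hetero, and meningeal and choroid plexus genes lower. All 15 astrocyte genes (median 0.19, adjusted p = 7.68e-05; adjusted p = 0.592 with an estimated correlation) were higher, with S100b at 0.21 (SE 0.0991) and Aldoc at 0.19 (SE 0.0884). All 13 microglia genes (median 0.18, adjusted p = 6.46e-05; adjusted p = 0.613 with an estimated correlation) were higher, with C1qb at 0.28 (SE 0.136) and Csf1r at 0.18 (SE 0.0898). All 13 meningeal fibroblast genes (median −0.46, adjusted p = 6.46e-05; adjusted p = 0.806 with an estimated correlation) were lower, with Igf2 at −0.70 (SE 0.246) and Col1a1 at −0.46 (SE 0.218). All 8 choroid plexus genes (median −2.36, adjusted p = 2.08e-08; adjusted p = 0.592 with an estimated correlation) were lower, with Prlr at −2.40 (SE 0.520) and Kl at −2.83 (SE 0.625); 6 passed with p adjusted over the list alone. Layer 5 neuron genes were lower for 7 of 9 (median −0.18, adjusted p = 0.0168; 0.735 with an estimated correlation), with Etv1 at −0.27 (SE 0.132) and Fezf2 at −0.29 (SE 0.156). Glucocorticoid-responsive genes were higher for 14 of 18 (median 0.24, adjusted p = 0.0212; 0.99 with an estimated correlation), with Ddit4 at 0.27 (SE 0.0999). Ribosomal protein genes were higher for 62 of 76 (median 0.06, adjusted p = 0.0457; 0.99 with an estimated correlation), with Rps14 at 0.16 (SE 0.103) and Rpl21 at 0.46 (SE 0.307). All 5 blood cell genes were higher (median 1.80, adjusted p = 0.0457; 0.99 with an estimated correlation), with Alas2 at 1.84 (SE 0.832). The cKO libraries on the list's side of the Hetero mean were 2 of 4 for glucocorticoid and for ribosomal genes, 3 of 4 for blood cell genes and 4 of 4 for each of the other 7 called lists. Retinoid genes were lower for 14 of 19 (median −0.13, adjusted p = 0.0256; 0.806 with an estimated correlation), with Ttr at −5.45 (SE 1.22), Aldh1a3 at −1.62 (SE 0.545) and Cyp26b1 at −0.52 (SE 0.211), and 1 gene, Ttr, past the threshold over the list alone. Ttr is also in the choroid plexus list, and without Hetero 2 its log2 fold change turned to 1.18. In the other 8 of the 10 called lists 0 genes passed over the list alone, and 0 passed over all genes in any list.

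The astrocyte, microglia, meningeal and immediate early calls between cKO and Hetero were kept without each of the 6 libraries in turn. Without cKO 2 the medians of 3 of these shrank, to 0.08 for astrocyte (adjusted p = 0.0125), 0.11 for microglia (0.0136) and −0.18 for meningeal genes (0.0242). The retinoid median was −0.20 without cKO 3. Of the 45 genes named in this comparison, 22 moved by over 1.5 times without some library. Without Hetero 2, Slc4a5 stood at −0.83, Col8a2 at −0.95, Aqp1 at −0.74, Prlr at −0.77, Kl at −0.09, Aldh1a3 at −1.05 and Ttr at 1.18. Ddit4 was at 0.16 without Hetero 1 and Col1a1 at −0.30 without cKO 2. Neurod6 was at −0.11 without cKO 2, −0.13 without cKO 4 and −0.36 without cKO 3. The choroid plexus call was lost without Hetero 2 (median −0.03, adjusted p = 0.5). Without Hetero 2 the adjusted p was also 0.325 for retinoid, 0.176 for layer 5 and 0.119 for blood cell genes, and without Hetero 1 it was 0.256 for glucocorticoid, 0.56 for ribosomal and 0.302 for blood cell genes. Without cKO 2 it was 0.195 for retinoid, 0.0834 for layer 5, 0.157 for blood cell and 0.379 for ribosomal genes, whose median turned to −0.03. Without cKO 4 it was 0.103 for retinoid and layer 5 genes and 0.391 for glucocorticoid genes. Without cKO 1 it was 0.185 for blood cell genes, and without cKO 3 it was 0.152 for blood cell and 0.151 for glucocorticoid genes. The 30 lists that did not pass had adjusted p from 0.135 to 0.977; in 11 of them the median, the mean and the test differed in sign, and in 0 of the 10 that passed.

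The responses of cKO and Hetero, both against the same 4 Loxp libraries, correlated across genes with Pearson r = 0.456 over 18455 genes, which are not independent replicates. Unchanged groups, with all 10 libraries simulated and the simulated Loxp libraries shared, gave a mean r of 0.406 and at most 0.438 in 100 simulations. Simulated genes varied independently and without structure between libraries, unlike measured genes. Their range therefore does not show whether 0.456 exceeds what shared controls give. The covariance was 0.0322 against 0.0306 simulated, a difference of 0.00162. With the Loxp libraries split so that each contrast had its own pair, r averaged −0.0165 over the 6 splits (−0.0642 to 0.0452). In those splits the median of the immediate early genes ran from −0.64 to −0.35 in Hetero and from −0.49 to −0.17 in cKO.

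Genes within 10 Mb of Rxra or Neurod6 were pooled over both loci, with Rxra and Neurod6 themselves included. These genes were compared with other genes by how often they reached an unadjusted p under 0.05. Pooling can dilute a difference at a single locus. In cKO against Loxp the genes near the loci that did so were 12 of 407 (2.95%) against 2.52% elsewhere (two-sided Fisher's exact p = 0.523). The values were 3.19% against 2.52% in Hetero against Loxp (Fisher's exact p = 0.422) and 2.21% against 1.73% in cKO against Hetero (Fisher's exact p = 0.439). edgeR called 0 of these genes in each comparison. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had a mean log2 CPM above 0 in 1 of 4 Loxp, 0 of 2 Hetero and 2 of 4 cKO libraries, so sex was not balanced between genotypes.

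The authors' deposited test results were read beside these values. They hold 0 of 29220 genes at an adjusted p under 0.05 in cKO against Loxp, where the smallest was 0.071. In Hetero against Loxp they hold 25 of 27904, 14 higher and 11 lower. Of the 25, 6 belong to the immediate early list (Fos, Fosb, Egr1, Ier2, Sik1 and Trib1), all lower, and 4 to the choroid plexus list (Ttr, Otx2, Sostdc1 and Kcne2), all higher. The deposited log2 fold changes and those fitted here correlated with r = 1 across the 18455 genes tested in both.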

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

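In this part, the tests of leaving out 1 library, of layer markers, of cKO against Hetero, of splits for the number of called genes and of the choroid plexus list were chosen after the result was seen. The tests of clock genes, of splits for the immediate early list and for unadjusted p-values, and of the library labelled Loxp 4 were set beforehand.

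The immediate early list lay lower in cKO than in Loxp, and the tables bear on some explanations. Leaving out 1 library at a time kept its median at or below −0.23 (without Loxp 4), which argues against 1 library. The 34 layer markers of excitatory neurons showed no fall, with a median of 0.01 (bootstrap interval over genes −0.0325 to 0.0498). That interval leaves out the spread between libraries, which for the layer 6 and subplate list had an SD of 0.242 in Loxp and 0.294 in cKO. A loss of excitatory neurons within that spread stays open. A fall graded by the Rxra alleles deleted would put cKO below Hetero, but cKO lay 0.212 above it on the log2 scale, beyond the SD of cKO (0.0849), with an exact p = 0.0667, the smallest possible. With 2 Hetero libraries that test could not reach 0.05. Hetero 1 and Hetero 2 stood at −0.51 and −0.57, and cKO 1 and cKO 2, of the same numbers, lay nearest to them at −0.41 and −0.40. Replicate number may thus enter the gap. The time of day at dissection stays open, since the arms of the clock differed by 0.058 (SE 0.16, exact p = 0.714), and chance was not excluded, since 4 of 35 splits of the 8 libraries gave a median as far from 0 as the real −0.34, the farthest other lying 0.40 from 0 for Loxp 1, Loxp 3, Loxp 4 and cKO 3 against the rest. Nex-cre itself may be a candidate explanation, since both Cre groups lay lower, but it cannot be told apart from deletion of 1 or both alleles or from handling before dissection, as no group carried Nex-cre without floxed Rxra.

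The choroid plexus list was higher in Hetero in 1 library. Hetero 2 lay 2.78 above the next highest library on the log2 scale, and Ttr, Kl, Clic6 and Folr1, all listed beforehand, stood there at 699, 13.9, 8.81 and 6.29 CPM. This is consistent with choroid plexus tissue in that library, which no sort removed. Hetero 1 minus the highest Loxp or cKO library was −0.403, which argues against an effect of the Hetero genotype on the list as a whole, though it rests on 1 library. In Hetero 1, Ttr, Kl, Clic6 and Folr1 lay within the range of the Loxp and cKO libraries. Col8a2 lay above it, at 1.58 CPM against at most 0.993, and Slc4a5, Aqp1 and Prlr only slightly so.

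Neurod6 in the library labelled Loxp 4 stood at 34.9 CPM, against 55.7 to 66.7 in the other Loxp libraries and 22.9 to 38.1 in the Cre libraries. Whether it came from a mouse with Cre stays open: of the 50 genes that best parted the other Loxp libraries from the Cre libraries, 52% put it nearer the Loxp mean. The other Loxp libraries, placed the same way, gave 54%, 28% and 44%, so the test does not tell a Loxp library from a Cre library. Its immediate early level, 0.26, was the highest of the 10 libraries (Cre libraries −0.57 to −0.23), while Loxp 2 lay among the Cre libraries at −0.34. The difference between the groups in this list was computed with the library labelled Loxp 4 in Loxp. Its level therefore does not bear on the label of the library labelled Loxp 4. Gm3279, a noncoding gene beside Neurod6 that was chosen after its values were seen, stood at 0.319 CPM in that library, 0.0478 to 0.197 in the other Loxp libraries and 0.502 to 1.13 in the Cre libraries.

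In cKO against Loxp the real split called 0 genes, so each of the 35 splits called at least as many and their count decides nothing about chance; the highest other called 1. For unadjusted p-values under 0.05 chance was not excluded, as 29 of 35 splits gave as many as the real 466. The highest other, 1909, set Loxp 1, Loxp 2, cKO 1 and cKO 2 against the libraries numbered 3 and 4. The other splits that kept equal numbers together gave 1690 and 1558, and splits that did not gave up to 1792. Counts this far above the real one point to a structure of the samples. Each of the 8 libraries correlated best with the library of its own number. The split that gave 1792 parted the libraries numbered 1 and those numbered 2, but kept numbers 3 and 4 together. Striatal neuron genes, chosen after their values were seen, lay at 0.87, −1.26, 0.65 and −0.26 in Loxp 1 to 4. They lay at 0.76, −1.20, 0.09 and −0.05 in cKO 1 to 4, as log2 levels relative to the Loxp mean. What the structure follows was not tested.

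Among groups of 4 libraries, a library far from the other three was found in 11 of 112 groups tested, by a gap above Dixon's 95% critical value for 4 samples, where chance gives 5.6. cKO 2 was that library in 7 of them, given here as log2 levels relative to the Loxp mean. It lay at 0.23 for LXR and PPAR targets (others −0.01 to 0.01), −0.27 for potassium channels (0.03 to 0.07), −0.42 for layer 6 and subplate (0.12 to 0.20), 0.60 for oligodendrocyte precursor (−0.14 to −0.10), −1.72 for meningeal fibroblast (0.04 to 0.12) and 0.17 for thalamic neuron genes (−0.09 to −0.06). Its mitochondrial share was 3.58% (others 3.15% to 3.20%). It also stood apart on the first principal component (21.8% of the variance) at 55.5, with the other libraries at −26.2 to 9.67. Loxp 2 lay at −0.18 for receptors that pair with RXR (others 0.05 to 0.07) and 0.23 for endothelial genes (−0.08 to −0.07). Loxp 1 lay at 0.25 for meningeal fibroblast genes (−0.11 to −0.05), and the library labelled Loxp 4 at −3.88 for blood cell genes (0.90 to 1.82). In cKO the lowest library for blood cell genes was cKO 4, at −1.65. No explanation was tested for these.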

How the results depend on the processing

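In this part, the robust prior and the newer residual deviances were chosen after the data were seen; edgeR called 0 genes in each comparison with either (unadjusted p under 0.05 for 459, 442 and 300 genes, and for 498, 473 and 336, in the order cKO against Loxp, Hetero against Loxp, cKO against Hetero). Over all alternatives, 220 values of the main results kept their direction and their side of the threshold, or moved little, while 22 moved, 2 reversed, 4 no longer passed and 2 came to pass; 2883 values of the other named genes did; 57 of the latter came to pass the threshold in the same direction and 2 reversed.

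With no low-count filter, edgeR tested 32197 genes and called 32, 68 and 39 in that order; the prior degrees of freedom were 89.8 in place of 6.32, so the spread of each gene was pulled closer to the common trend. Neurod6 passed with this setting, at −0.89 in cKO against Loxp (adjusted p over its alternatives 2.96e-07 to 1) and −0.68 in Hetero against Loxp (0.00966 to 1), and 5 lists passed in cKO against Hetero in place of 10, the cause of which was not tested. DESeq2 called 20 genes in Hetero against Loxp and 3 in cKO against Hetero. The replicate block called 1 gene each in cKO and Hetero against Loxp (Arc) and put Rxra at 0.0033 in Hetero against Loxp; 1 surrogate variable called 1 gene in cKO against Loxp (mt-Nd4l). For DESeq2, the block and the surrogate variable the cause was not tested.

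With an estimated correlation, 0 lists passed in each comparison, and with fry 0. The immediate early median, −0.34 in cKO and −0.54 in Hetero, is unmoved by construction; its adjusted p was 0.807 and 0.83 in cKO (1.48e-26 to 0.83 over its alternatives) and 0.297 and 0.336 in Hetero (4.22e-35 to 0.336). The estimate lets the listed genes vary together between libraries, and fry is set against that spread. With other alternatives that median was −0.34 to −0.32 in cKO and −0.54 to −0.38 in Hetero, the replicate block (−0.32 and −0.38) and the Xist covariate (−0.34 and −0.53) included.

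Leaving out 1 library gave 0 to 1 called genes in cKO against Loxp (1 without cKO 2), 0 to 15 in Hetero against Loxp and 0 to 14 in cKO against Hetero (the highest without Hetero 1). Lists called ran from 4 (without Loxp 3) to 13 (without cKO 4; 10 without cKO 2) in cKO against Loxp, and from 7 (without Hetero 2; 9 without Hetero 1) to 16 (without Loxp 3) in Hetero against Loxp. Rxra in Hetero against Loxp ran from −0.19 (without Hetero 2) to 0.0103 (without Loxp 4). Cnp in Hetero against Loxp turned from −0.45 (without Hetero 1) to 0.091 (without Hetero 2), and Ttr in cKO against Hetero from −6.45 to 1.18 likewise. The cause was not tested beyond the library left out.

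Replicate numbers recur between genotypes. Libraries with the same number, with group means removed, correlated with r = 0.042 to 0.32. Not all lay above the threshold of 0.1, so they were not taken as pairs. Yet 8 of 8 Loxp and cKO libraries correlated best with the library of their own number, which points to a shared structure. The main p-values, the exact tests and the splits take no account of it. With the replicate number as a block, 645 genes reached an unadjusted p under 0.05 in cKO against Loxp by edgeR, in place of 466. The correlation of the cKO and Hetero responses was 0.456 to 0.505 over 3 alternatives, and the shares near the loci were 2.58% to 3.79% with windows of 5 and 20 Mb. The highest, in Hetero against Loxp at 20 Mb, stood against 2.50% elsewhere (Fisher's exact p = 0.0593); the other windows gave exact p of 0.143 to 0.501. At this depth and number of samples, 42.0% (cKO) and 28.7% (Hetero) of simulated changes of 1.5-fold were recovered, so changes of that size can be missed. The simulated libraries had no shared structure. In cKO against Loxp the measured data gave 466 genes at an unadjusted p under 0.05 by edgeR, where chance gives 922.8. Recovery in the measured data may thus be lower than simulated, for larger changes too.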

Other observations

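Some genes varied between libraries beyond the comparisons above and were chosen after their values were seen. Erdr1 stood at 13.9, 10.4, 2.40 and 13.7 CPM in Loxp, 27.0 and 39.3 in Hetero, and 12.7, 53.4, 20.3 and 46.6 in cKO. Mid1 stood at 5.68, 1.87, 3.22 and 4.55 CPM in Loxp, 8.63 and 17.8 in Hetero, and 5.28, 26.4, 25.2 and 15.9 in cKO. Penk, which is in the striatal neuron list, ran from 14.5 to 106 CPM over the 10 libraries, with 18.7 in Loxp 2 and 14.5 in cKO 2. Grouping Hetero with cKO, which was also chosen afterwards, the level of the immediate early list differed between the 6 Cre and the 4 Loxp libraries with an exact two-sided permutation p = 0.0143, where 0.00476 was the smallest possible, and adjusted p = 0.286 over the lists. The level of the mitochondrially encoded list was higher in each of the 6 Cre libraries than in every Loxp library, with the smallest exact p possible, 0.00476 (adjusted p = 0.19 over the lists), but Hetero 1 lay at 0.123 and Loxp 2 at 0.119. That level gives each gene the same weight, whatever its count. The share of counts on mitochondrial genes did not part the groups. It was 2.80% to 3.68% in Loxp, 3.02% and 3.065% in Hetero, and 3.15% to 3.58% in cKO, with the highest in Loxp 2. In Hetero against Loxp the list did not pass camera (7 of 13 genes higher, median 0.05, adjusted p = 0.174), and of its 7 genes without a near-identical nuclear copy 2 were higher (median −0.02). For cKO against Loxp alone its exact p was 0.0286, again the smallest possible, and its adjusted p = 1.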
